A study of Drosophila melanogaster with 6 samples.

How the data were processed

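RNA was measured in 6 libraries of whole Drosophila melanogaster adults that carried an osa RNAi construct under the C564-GAL4 driver. Per the labels, 3 libraries came from non-infected flies and 3 from flies infected with Micrococcus luteus for 24 h, each library from a separate biological replicate (A, B or C) of 5 flies. Polyadenylated RNA was made into strand-marking libraries (TruSeq Stranded mRNA), per the labels' protocols, and each library was sequenced in 1 lane. A library without the RNAi construct and a library of wounded but uninfected flies were not analysed here.

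The deposited values are raw counts of reads per gene, not normalised. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.0.10 and Subread 1.5.0 were used with the BDGP6 genome. Per the file headers, the counts were made with featureCounts v1.5.0 over exons summed by gene identifier. The header commands give no option for strand, for multiply mapped reads or for reads that overlap several genes, so the program's defaults applied: strand was not used, and reads with several mapping positions or several overlapping genes were not counted. Near-identical copies are therefore undercounted, and reads of overlapping or antisense genes cannot be separated. IM18, BaraA1 and BaraA2 had 0 counts in every library, as did the 37 genes of the mitochondrial genome.

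Each file held 17558 genes. Symbols were assigned by gene identifier for 17252 genes and, for a further 213, by a unique match of position to the BDGP6.54 annotation on the same strand, with a reciprocal overlap of at least 0.9 and a shared exon boundary. The remaining 93 genes kept their identifier. Of the identifiers shared with that annotation, 16959 (98.3%) had identical coordinates. Coordinates are printed as the deposited files give them (BDGP6).

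Total counts per library ran from 9109561 to 19439523. Low-count genes were removed with filterByExpr (minimum count 10, minimum total 15), which left 12905 genes that held at least 99.9% of the counts of each library. Scale factors came from TMM and ran from 0.976 to 1.04. The groups were compared with edgeR 4.0.16 (quasi-likelihood F test, robust = TRUE, two-sided) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Expression levels are TMM-normalised CPM (counts scaled to a common library total), given as mean ± SD over 3 libraries. "Rose" and "fell" are used for genes with an adjusted p under 0.05. The ratio of a gene with 3 or fewer counts in a group is given with an exact (Clopper-Pearson) 95% interval, which covers counting error only.

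Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 3 tested members, 26 in all, were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), with camera with an estimated correlation, and with fry, each adjusted over the 26 lists. For each list the number of members past the threshold is given both over all genes and adjusted over the list alone. The named genes were those with an adjusted p under 0.05, an average log2 CPM above 1 and no overlap between the CPM of the groups. Of these, the rule took the 10 largest rises, the 10 largest falls and the 5 smallest p-values in each direction. It also took up to 4 members of each list with the smallest p and its most abundant member, and it allowed every member of the Brahma, immune peptide, Toll, Imd, JAK-STAT, yolk and iron lists. Other genes are named as chosen after their values were seen.

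The alternatives were RLE, upper-quartile and no scale factors, DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in 3 libraries, robust = FALSE, a replicate block, leaving out each library in turn, and glmTreat against a fold of 1.5. The alternative without scale factors was chosen after seeing the data. The procedure was tested on simulated counts for the same 12905 genes and the same comparison, with 200 genes changed by known folds. Of these it recovered 82% at a fold of 1.5, 96% at a fold of 2 and 100% at a fold of 4 or 16. Of its calls, 5.24% were unchanged genes. A further 20 genes were changed by a fold of 1.3 as a planted list, which camera called. Their recovery as single genes was not tabulated. The simulated spread followed the trend with abundance, without gene-specific spread or outlier libraries, and a smaller share of genes changed. These rates may therefore differ in the data. Within each group, no pair of libraries was a duplicate: the variance of their counts was 4.87 to 9.41 times that of sampling noise.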

Results

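The series asked how osa RNAi flies differ with and without bacterial infection. Osa is the signature subunit of the BAP form of the Brahma (SWI/SNF) chromatin remodelling complex, and C564-GAL4 is a driver active in the fat body and other tissues. M. luteus is a Gram-positive bacterium whose cell wall activates the Toll pathway. The 3 non-infected libraries held 15202667, 16885875 and 9109561 counts (replicates A, B and C), and the 3 infected libraries 16625848, 14341554 and 19439523 counts. Between 14625 and 15045 genes had at least 1 count in a library. Every library came from RNAi flies and infection also meant a wound and 24 h, so the comparison is between infected and non-infected RNAi flies and estimates neither the effect of the knockdown nor that of the bacterium apart from injury and time.

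The targeted gene was expressed at similar levels in all libraries. Osa (FBgn0261885, 3R, 17687818 to 17718350) stood at 144, 147 and 159 CPM in the non-infected replicates A, B and C and at 154, 166 and 171 CPM in the infected replicates. Its log2 fold change of 0.13 ± 0.07 (SE, n = 3 per group) did not pass the test (edgeR, adjusted p = 0.178). Of the 12 Brahma complex members tested, Bap111 alone passed (log2 fold change 0.24 ± 0.07), and it was also alone when adjusted over the list alone. Its adjusted p of 0.0206 rose above the threshold without non-infected replicate A (0.0902) or C (0.0614), without infected replicate A (0.0753) or B (0.0688), and without scale factors (0.0785). Polybromo passed with RLE factors alone (0.0452, against 0.0571 in the main fit). The catalytic subunit brm had a log2 fold change of 0.08 ± 0.07, mor 0.06 ± 0.07 and Snr1 0.02 ± 0.09. The list as a whole did not differ from other genes (camera, adjusted p = 0.439). How far osa was knocked down cannot be read from these libraries, which all carry the construct.

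Infection was accompanied by a large rise of secreted immune peptides and by a broad fall of metabolic, muscle and male accessory gland transcripts. Of 12905 genes tested, 1328 rose and 1652 fell (2980 together, or 23.1%). At least a 2-fold change was reached by 242 rising and 261 falling genes, and at least a 16-fold change by 33 rising and 4 falling genes. The groups did not overlap at 4782 genes (37.1%), where chance gives 10%. The first principal component held 70.9% of the variance and separated the groups. The lowest correlation between libraries of a group was 0.991 and the highest between groups 0.973. Without scale factors, 992 genes rose and 2256 fell, and the median of all genes stood at -0.07 on the log2 scale against -0.01 with TMM. With glmTreat against a fold of 1.5, 248 genes rose and 283 fell. Of the 26 lists tested, 10 stood higher and 8 lower than other genes with camera, and 4 of the 18, all higher, held with an estimated correlation.

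**Figure D1:**
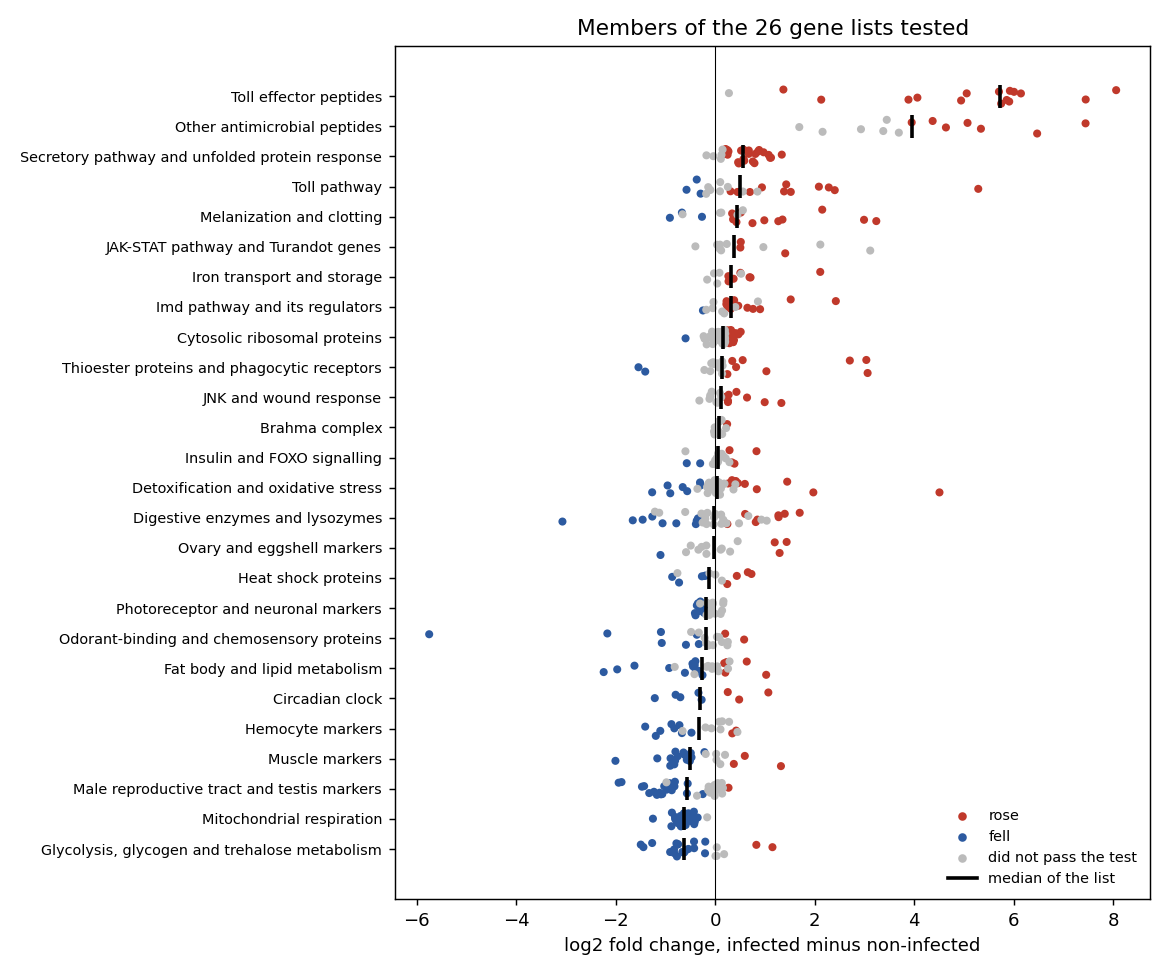
Log2 fold change (infected minus non-infected) of each tested member of the 26 gene lists, with a point per gene, red for genes that rose, blue for genes that fell and grey for genes that did not pass the test, and a black bar at each list's median. The median ran from 5.73 for the Toll effector peptides to -0.62 for the glycolysis and mitochondrial respiration lists.

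Toll effector peptides, the short secreted peptides induced through the Toll pathway, showed the largest rise. Of 16 tested members 15 rose, and 16 passed when adjusted over the list alone, with a median log2 fold change of 5.73 (camera, adjusted p = 2.91e-257, and adjusted p = 0.0049 with an estimated correlation). Drosomycin (Drs, FBgn0010381, 3L, 3369556 to 3369942), an antifungal peptide, went from 37.9 ± 3.4 to 6640 ± 77.9 CPM (SD, n = 3 per group), a 175-fold rise (log2 fold change 7.45 ± 0.11, adjusted p = 2.78e-21). The Bomanin genes on 2R rose together. BomT1 (18381393 to 18381844) had a log2 fold change of 8.06 ± 0.12, BomBc1 (18382704 to 18383235) 6.15 ± 0.10, BomBc2 (18384824 to 18385589) 6.01 ± 0.12 and BomS1 5.86 ± 0.12. The Daisho peptide Dso1 reached 10822 ± 484 CPM from 180 ± 38.8, and Dso2 rose by a log2 fold change of 5.92 ± 0.10. BaraC, at 0.28 ± 0.13 (adjusted p = 0.135), did not pass over all genes. The list's share of all counts went from between 0.0676 and 0.0963% in the non-infected libraries to between 3.38 and 3.64% in the infected libraries. The models of BomS4 and BomBc2 overlap, and reads in the overlap were not counted for either.

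The other antimicrobial peptides were also higher after infection, with more spread between the infected libraries. Of 13 tested members 7 rose and 6 did not pass, and 9 passed adjusted over the list alone (median log2 fold change 3.95, camera adjusted p = 7.24e-47, and adjusted p = 0.0506 with an estimated correlation). Drosocin (Dro) went from 12.5 ± 3.2 to 2143 ± 239 CPM, metchnikowin (Mtk) from 14.5 ± 2.6 to 1272 ± 138 CPM, CecA2 from 1.99 ± 0.80 to 66.1 ± 7.4 CPM and DptB from 33.8 ± 6.0 to 838 ± 131 CPM. AttA rose by a log2 fold change of 4.37 ± 0.40. DptA (3.95 ± 0.54) and AttC (5.34 ± 0.76) rose too, but DptA missed the threshold without non-infected replicate A (adjusted p = 0.0505) or B (0.052) and with the replicate letter as a block (0.0824), and AttC without non-infected replicate A (0.0575) and with the block (0.10025). Infected replicate B stood above the other infected libraries for AttB (193 CPM against 22.6 and 40.0), CecA1 (237 against 59.0 and 93.3), CecC (39.4 against 5.86 and 12.3), CecB (13.4 against 2.71 and 5.89), Def (12.5 against 3.51 and 4.68) and AttD (22.8 against 0.43 and 3.68). None of these 6 passed in the main fit. Infected replicate B was also highest for genes that rose, such as AttC (2153 CPM against 774 and 925), DptA (444 against 183 and 207) and AttA (270 against 132 and 175). The list's share of all counts was 0.815% in infected replicate B, against 0.504% in A and 0.542% in C. Without infected replicate B, CecA1 passed with a log2 fold change of 1.40, AttB with 1.96, CecC with 1.90, CecB with 2.97 and Def with 0.98, and AttC kept 4.75. CecB also passed without infected replicate A (4.08). With the replicate letter as a block CecB, CecC and Def passed, and with DESeq2, or with robust = FALSE in edgeR, all 6. AttA and AttB are near-identical copies, so their separate values are uncertain. The cecropin genes are copies that are alike to differing degrees, so their separate values may be uncertain too.

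**Figure D2:**
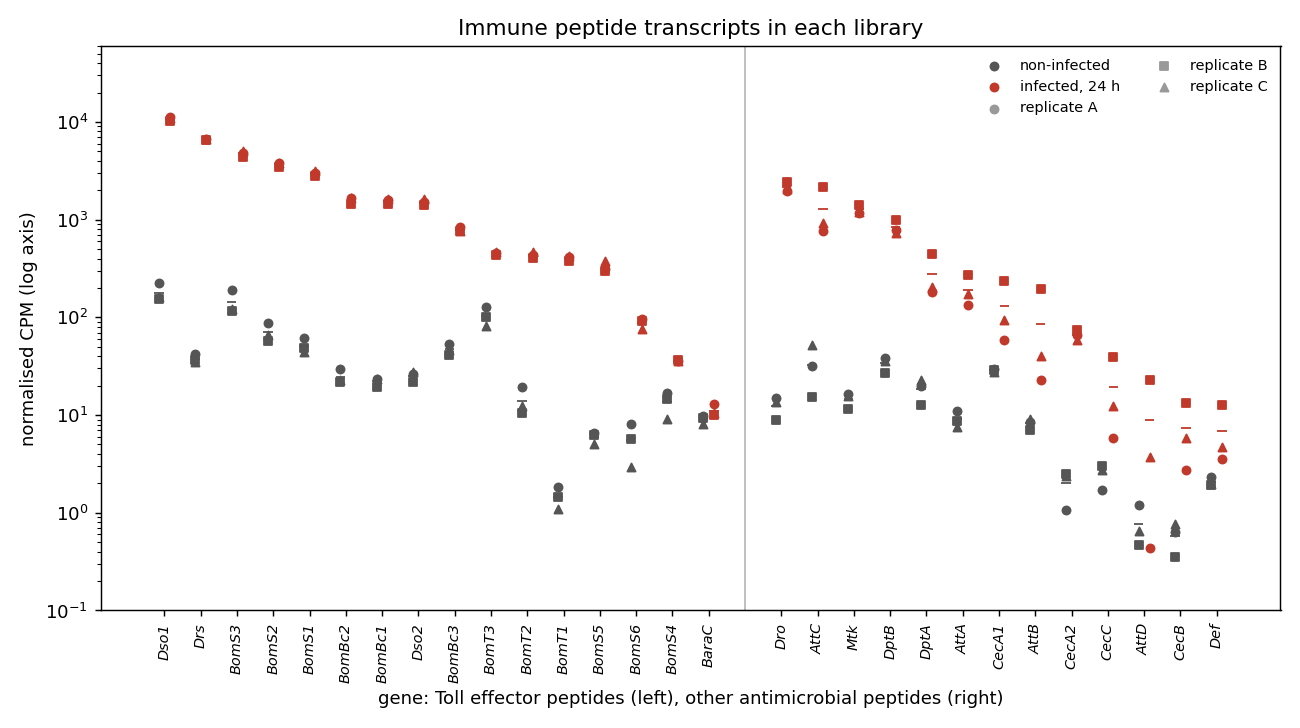
Normalised CPM (log axis) of Toll effector peptides (left) and other antimicrobial peptides (right) in each non-infected (grey) and infected (red) library, with a symbol per replicate and a short line at each group's mean. Drs moved from about 37.9 to 6640 CPM, and infected replicate B stood highest for AttB at 193 CPM.

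Transcripts of the Toll pathway itself rose in part. Of 22 tested members 11 rose and 3 fell, against 13 and 4 adjusted over the list alone (median log2 fold change 0.50, camera adjusted p = 4.05e-20, and adjusted p = 0.00642 with an estimated correlation). GNBP-like3 rose from 45.1 ± 6.1 to 1748 ± 69.3 CPM. The Spätzle-processing enzyme SPE rose by a log2 fold change of 2.40 ± 0.08, the serpin nec by 2.28 ± 0.08, the recognition receptor PGRP-SA by 2.08 ± 0.08, the inhibitor cact by 1.52 ± 0.07 and the kinase pll by 1.43 ± 0.11. The receptor gene Tl (0.94 ± 0.07) and the transcription factor genes Dif (0.70 ± 0.07) and dl (0.45 ± 0.06) rose as well. The protease gene psh fell by 0.58 on the log2 scale, GNBP3 by 0.37 and the adaptor gene Myd88 by 0.29. Among the 19 tested members of the Imd pathway and its regulators, 11 rose and 1 fell, with the same counts adjusted over the list alone (median log2 fold change 0.31, camera adjusted p = 1.20e-05, and adjusted p = 0.0592 with an estimated correlation). The NF-κB factor gene Rel rose from 124 ± 4.8 to 356 ± 19 CPM, the adaptor gene imd had a log2 fold change of 0.90 ± 0.08, and PGRP-SB1 2.42 ± 0.23. Of the negative regulators, PGRP-LF rose (0.76 ± 0.14), and pirk (-0.18 ± 0.09), PGRP-LB (0.40 ± 0.26), casp (-0.04 ± 0.06) and PGRP-SC2 (0.86 ± 0.32) did not pass, though PGRP-SC2 did with DESeq2 (adjusted p = 0.0465) and with robust = FALSE (0.00267).

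Melanization and clotting genes were mostly higher: of 19 tested, 11 rose and 3 fell, against 13 and 4 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 4.18e-13, and adjusted p = 0.0111 with an estimated correlation). The serpin gene Spn28Dc rose from 29.0 ± 0.4 to 274 ± 21 CPM. The protease genes MP1 and Sp7 had log2 fold changes of 2.15 ± 0.07 and 1.35 ± 0.07, and the melanin pathway gene yellow-f 2.99 ± 0.11. The prophenoloxidase genes went both ways: PPO1 fell by 0.91 and PPO2 by 0.67 on the log2 scale, while PPO3 rose by 1.27 ± 0.25 (the 3 chosen after their values were seen). Of 20 thioester proteins and phagocytic receptors, 8 rose and 2 fell, against 8 and 3 adjusted over the list alone (camera adjusted p = 2.70e-08, and adjusted p = 0.0222 with an estimated correlation). NimB3 rose by a log2 fold change of 3.06 ± 0.08, Tep2, an opsonin-like protein, by 3.04 ± 0.09, NimB1 by 2.71 ± 0.09 and NimB2 by 1.03 ± 0.06.

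Hemocyte markers stood lower than other genes: of 18 tested, 8 fell and 2 rose, against 10 and 4 adjusted over the list alone (median log2 fold change -0.34, camera adjusted p = 2.65e-04, and adjusted p = 0.208 with an estimated correlation). The members with the smallest p-values encode secreted proteins, which other tissues such as the fat body can also make. Nplp2 fell by 1.41 on the log2 scale, Glt by 1.20, and the collagen genes Col4a1 by 0.88 and vkg by 0.82. The phagocytic receptor genes eater (0.42 ± 0.11) and Sr-CI (0.34 ± 0.10), chosen after their values were seen, rose. In the JAK-STAT and Turandot list of 12, Socs36E (0.51 ± 0.09), the receptor gene dome (0.50 ± 0.09) and the cytokine gene upd3 (1.41 ± 0.37) rose, with the same 3 adjusted over the list alone. The adjusted p of upd3 was 0.0092, and 0.0722 without non-infected replicate B. The value of upd3 without non-infected replicate A was 2.17. The list did not pass (camera, adjusted p = 0.0975), but it did without infected replicate B (0.0216). The stress peptide gene TotA stood at 76.1 CPM in infected replicate A against 7.01 and 14.2 in B and C, and TotC at 29.4 against 0.567 and 2.05. Without infected replicate A, the log2 fold change of TotA was -0.61 and that of TotC 0.18, against 0.97 ± 1.11 and 3.12 ± 1.89 with all libraries, and none of these values passed the test. TotC passed with robust = FALSE (adjusted p = 0.0419). Of 17 JNK and wound response genes 8 rose and 9 did not pass, also adjusted over the list alone, with Gadd45 at 1.33 ± 0.09 and the transcription factor gene Ets21C at 0.99 ± 0.15 (camera adjusted p = 0.0407, 0.0601 without non-infected replicate B, and adjusted p = 0.178 with an estimated correlation).

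Genes of the secretory pathway and the unfolded protein response rose together. Of 29 tested members 24 rose and 5 did not pass, against 25 that rose and 1 that fell adjusted over the list alone (median log2 fold change 0.57, camera adjusted p = 1.33e-14, and adjusted p = 0.112 with an estimated correlation). The translocon genes TRAM (1.34 ± 0.08) and Sec61beta (1.10 ± 0.07), the signal recognition particle receptor gene SrpRbeta (1.12 ± 0.09) and SsRbeta (0.86 ± 0.07) had the smallest p-values. The most abundant member, the protein disulfide isomerase gene Pdi, rose by 0.79 ± 0.08. Of 92 cytosolic ribosomal protein genes 27 rose and 1 fell, against 36 and 2 adjusted over the list alone, by small amounts (median log2 fold change 0.15, camera adjusted p = 0.00132, and adjusted p = 0.665 with an estimated correlation). RpL35A had the smallest p in that list (0.51 ± 0.07). Of 12 iron transport and storage genes 7 rose and 5 did not pass, also adjusted over the list alone (camera adjusted p = 9.56e-05, and adjusted p = 0.0592 with an estimated correlation). Transferrin 1 (Tsf1), an abundant secreted iron-binding protein, went from 1467 ± 140 to 6336 ± 413 CPM, and the ferritin subunit genes Fer2LCH and Fer1HCH had log2 fold changes of 0.69 ± 0.07 and 0.51 ± 0.07.

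Heat shock, detoxification and insulin genes moved in both directions, and none of these lists passed. Of 13 heat shock genes 4 rose and 5 fell, against 4 and 6 adjusted over the list alone (median log2 fold change -0.12, while the camera statistic was positive with an adjusted p of 0.936). Hsp83 (0.73 ± 0.07) and the constitutive chaperone gene Hsc70-4 (0.66 ± 0.07) rose, and Hsp23 and Hsp70Bb fell by 0.73 and 0.87 on the log2 scale. Of 39 detoxification and oxidative stress genes 10 rose and 7 fell, against 12 and 7 adjusted over the list alone (camera adjusted p = 0.297). Cyp12d1-p fell by 1.27 and the mitochondrial superoxide dismutase gene Sod2 by 0.56, GstE1 rose by 0.60 ± 0.07, and the metallothionein gene MtnD, chosen after its value was seen, rose from 3.8 ± 1.2 to 91 ± 18.2 CPM. Of 18 insulin and FOXO genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.311). ImpL2, a secreted insulin-binding protein, rose by 0.83 ± 0.09 and the translational repressor gene Thor by 0.39 ± 0.07, and Ilp6 fell by 0.57.

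Nuclear genes of mitochondrial respiration fell almost throughout. Of 36 tested members 35 fell and 1 did not pass, and 36 fell adjusted over the list alone (median log2 fold change -0.62, camera adjusted p = 3.59e-24, and adjusted p = 0.178 with an estimated correlation). Cytochrome c (Cyt-c-p) went from 1247 ± 71 to 523 ± 37.7 CPM and the ATP synthase gene ATPsynbeta from 2431 ± 59.9 to 1329 ± 59 CPM. Of 25 genes of glycolysis, glycogen and trehalose metabolism 19 fell and 2 rose, also adjusted over the list alone (median log2 fold change -0.62, camera adjusted p = 2.35e-10, and adjusted p = 0.188 with an estimated correlation). The trehalose synthesis gene Tps1 went from 2718 ± 82.5 to 999 ± 11.7 CPM, Gapdh1 fell by 1.27 and Gpdh1 by 0.82 on the log2 scale. The 2 genes that rose, fbp (0.83 ± 0.06) and Pepck2 (1.15 ± 0.17, chosen after its value was seen), encode enzymes of gluconeogenesis. Muscle markers fell beside them: of 23 tested, 15 fell and 3 rose, also adjusted over the list alone (median log2 fold change -0.51, camera adjusted p = 1.41e-06, and adjusted p = 0.311 with an estimated correlation). Myosin heavy chain (Mhc) went from 3065 ± 338 to 1815 ± 131 CPM and Mlc1 fell by 0.90. Act88F (1.32 ± 0.29), Act57B (0.59 ± 0.10) and TpnC73F (0.37 ± 0.09), named after their values were seen, rose, and the actin genes share much of their sequence.

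Fat body and lipid genes stood lower: of 27 tested, 12 fell and 5 rose, against 14 and 6 adjusted over the list alone, and 14 fell and 2 rose with upper-quartile factors or without scale factors (median log2 fold change -0.26, camera adjusted p = 0.0102, and adjusted p = 0.311 with an estimated correlation). The fatty acid synthesis gene ACC fell by 0.93 on the log2 scale and Lsp1beta by 1.97. Apolipophorin (apolpp), the main lipid carrier of the hemolymph, went from 3477 ± 188 to 735 ± 167 CPM (chosen after its value was seen). The desaturase gene Desat1 rose from 1635 ± 120 to 3326 ± 89.5 CPM, and the lipase gene bmm rose by 0.63 ± 0.07. Of 39 digestive enzyme and lysozyme genes 8 rose and 9 fell, against 10 and 10 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.489, with a positive statistic beside a median of -0.02 and a mean of -0.06). The amylase genes Amy-p (1.70 ± 0.13) and Amy-d (1.27 ± 0.11), near-identical copies, rose.

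Male reproductive transcripts fell as a list: of 36 tested, 19 fell and 1 rose, against 20 and 2 adjusted over the list alone (median log2 fold change -0.56, camera adjusted p = 4.18e-13, and adjusted p = 0.0943 with an estimated correlation). The seminal protein gene Acp36DE went from 1951 ± 269 to 724 ± 45.7 CPM, Acp53C14c fell by 1.47 on the log2 scale, Acp63F by 1.06 and the ejaculatory duct gene Dup99B by 0.98. The most abundant member, the sperm protein gene loopin-1, stood at 1375 ± 77.5 and 1424 ± 70.1 CPM and did not pass. The labels used here do not give the sex of the flies. Yolk protein transcripts were near 0, with 2 counts or fewer of Yp1 and 7 or fewer of Yp2 in every library and Yp3 at 8.28 ± 0.61 and 9.36 ± 0.38 CPM, too few for a list test. Of 14 ovary and eggshell genes, all at low levels, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.651, with a positive mean beside a median of -0.03), and yellow-g had the smallest p (1.20 ± 0.20) and passed under every alternative tabled for single genes, which leaves out glmTreat. The other 3 calls were lost without infected replicate C, with an adjusted p of 0.0606 for Cp7Fa and 0.0552 for Cp18, which rose, and 0.0649 for bam, which fell, and each was lost under further alternatives. Of 25 photoreceptor and neuronal genes 11 fell and 14 did not pass, against 13 that fell and 1 that rose adjusted over the list alone, by small amounts, with Syt1 at -0.41 ± 0.07. That list's camera adjusted p of 0.0427 went to 0.127 without non-infected replicate C, 0.0793 without infected replicate A and 0.0639 without infected replicate B, and to an adjusted p of 0.495 with an estimated correlation.

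Of 21 odorant-binding and chemosensory genes 7 fell and 2 rose, against 9 and 2 adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 0.003, and adjusted p = 0.332 with an estimated correlation). Obp99b (3R, 29716254 to 29716896) had the largest fall of the named genes in this comparison, from 784 ± 154 to 14.7 ± 3.9 CPM (log2 fold change -5.75 ± 0.27, adjusted p = 1.02e-04). All 8 circadian clock genes changed, also adjusted over the list alone. The clock repressor genes tim and per fell by 1.22 and 0.70 on the log2 scale and Pdp1 by 0.80, and the photoreceptor gene cry rose from 56.3 ± 7.0 to 118 ± 6.9 CPM. The other 4 members, named after their values were seen, were vri (-0.34 ± 0.06) and cwo (-0.27 ± 0.07), which fell, and cyc (0.48 ± 0.08) and Clk (0.25 ± 0.07), which rose. As members went both ways, the list did not pass (camera, adjusted p = 0.0928).

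**Figure D3:**
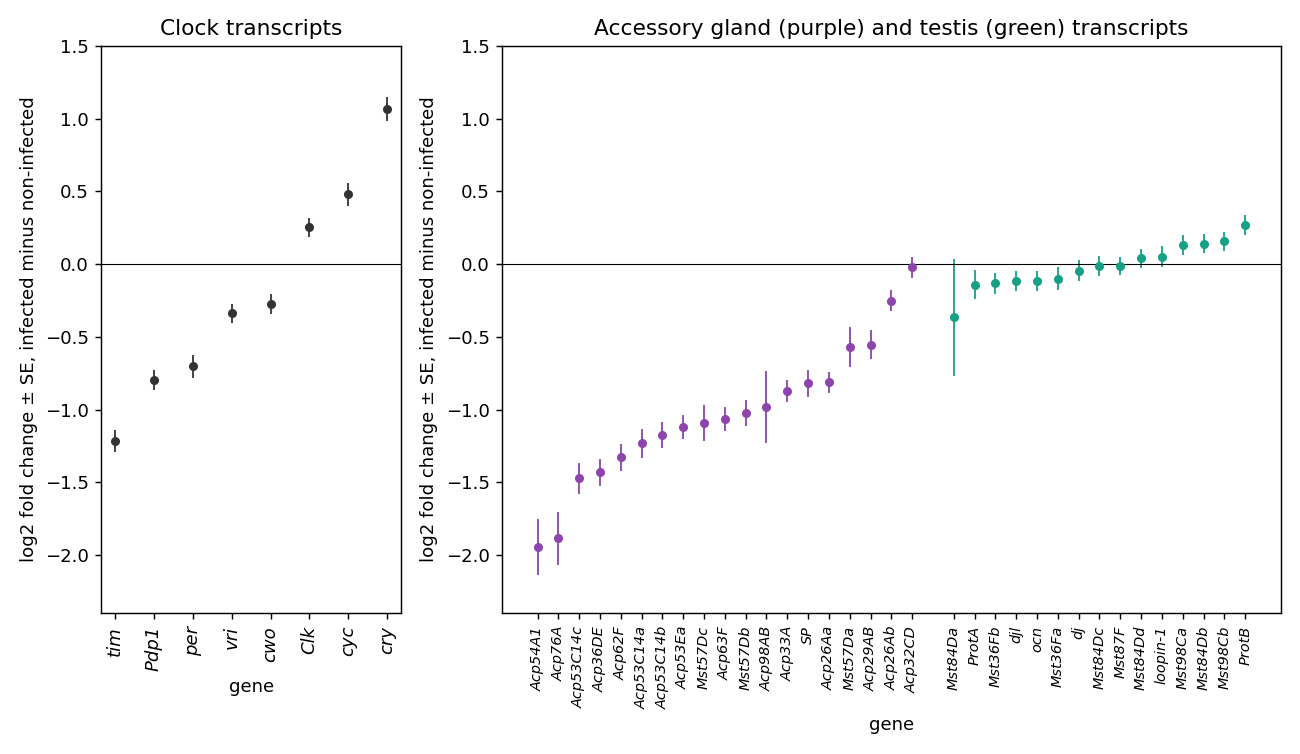
Log2 fold change ± SE (infected minus non-infected, 3 libraries per group) of the 8 clock genes (left) and of accessory gland (purple) and testis (green) transcripts (right). Accessory gland transcripts had a median of -1.06 and testis transcripts a median of -0.01.

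Several of the genes with the largest changes belonged to none of the lists. CG33462 (2R, 15696794 to 15698010) had 2 counts in the 3 non-infected libraries and 1075 in the infected ones, a ratio of 458 (95% interval 127 to 3791). Its fitted log2 fold change was 8.62, and 8.03 without non-infected replicate A. Without replicate B, which held both non-infected counts, no fold change can be measured. The X-linked gene sisA (X, 11321579 to 11322357), known as an embryonic sex determination factor, went from 0.331 ± 0.017 to 81.8 ± 12.0 CPM (log2 fold change 7.91 ± 0.18, adjusted p = 9.55e-17). CG4757 (3R, 11161207 to 11163498) rose from 50.1 ± 7.7 to 5660 ± 176 CPM and the stress-induced DNase gene Sid (3R, 28670704 to 28672021) from 1.58 ± 0.55 to 108 ± 5.0 CPM. Among falls of genes with an average log2 CPM above 1, CG2444 (X, 11704310 to 11705300) went from 41.5 ± 7.6 to 1.15 ± 0.58 CPM and CG34291 (3R, 26425290 to 26425781) from 4.33 ± 0.10 to 0.182 ± 0.051 CPM.

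Above the same level the next largest falls had log2 fold changes between -2.88 (CG30280) and -2.49 (CNMa, a neuropeptide gene), with phu, CG7214, lncRNA:CR30121 and CG17633 between them. CG16727, at -2.85 ± 0.50 with an adjusted p of 0.0211, missed the threshold without non-infected replicate B (0.0829) or C (0.0617) and without infected replicate C (0.0904) and with the replicate letter as a block (0.114), and its value was -3.46 without infected replicate A. The smallest p-values among falling genes belonged to CG42369 (460 ± 11 to 105 ± 7.4 CPM), Iris, derived from a retroviral envelope gene (55.9 ± 5.0 to 11.1 ± 0.8 CPM), the cytochrome P450 gene Cyp4ac1 (49.7 ± 4.0 to 12.3 ± 1.3 CPM), the ejaculatory bulb gene EbpII (1438 ± 65 to 521 ± 22 CPM) and Tps1.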

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

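The number of genes changed stayed within 1.5 times of 2980 under every alternative except a minimum fold: glmTreat against a fold of 1.5 left 531 genes, 248 rising and 283 falling, which by construction asks for larger changes. Leaving out each library gave 2337 to 2740 genes. RLE factors gave 2973, upper-quartile factors 3078, DESeq2 2544 and no filter on low counts 3012. Without scale factors 3248 genes were called (992 rising, 2256 falling) and the median gene stood at -0.07 on the log2 scale against -0.01 with TMM. Of the 2980 genes, 2483 were also called by DESeq2 and 2246 to 2520 when a library was left out, and none was called in the opposite direction under any alternative. The number of lists past the threshold, 18 (10 higher, 8 lower), was 18 with RLE factors, without scale factors and without a filter on low counts, 17 or 18 with a library left out, and 20 with fry, which asks another question. With fry the detoxification, clock and ovary lists passed too (adjusted p = 0.00693, 0.00127 and 0.037) and the ribosomal list did not (0.0573). Lists were not tested with upper-quartile factors or the stricter filter. With an estimated inter-gene correlation the number of lists was 4, with 4 higher and 0 lower. The estimate was 0.67 for the respiration list, 0.54 for the ribosomal list and 0.52 for the muscle list, against the preset 0.01. It was under the preset for the iron list (0.0051) and the JNK list (-9.28e-04), which also missed the threshold. For the iron and JNK lists a higher correlation was therefore not the cause, and the cause was not tested further. Lists that stayed past the threshold weakened too with an estimate under the preset. The unadjusted camera p of the Toll pathway list (estimate -0.018) went from 6.2e-21 to 4.9e-04. That of the melanization list (-0.026) went from 1.1e-13 to 0.00128. The drop from 18 to 4 lists therefore cannot be put down to correlation between genes alone. The log2 fold change of osa ran from 0.07 without scale factors to 0.17 without non-infected replicate C and passed under none of the alternatives run for single genes.

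The replicate letters showed no sign of pairing: deviations from the group means correlated at -0.06, -0.02 and 0.05 for the letters A, B and C. Libraries of different letters correlated at -0.05 to 0.07. Deviations within a group of 3 libraries sum to 0, so this check cannot exclude a shared cross, day or batch, which the labels do not give. With the replicate letter as a block, 2809 genes were called (1239 rising, 1570 falling) and 18 lists, and osa had a log2 fold change of 0.13. Of 212 named or nameable genes, 180 kept the same call under every alternative except glmTreat, which was compared by the number of genes only, and none that was called in either fit changed direction. Depth limits genes under about 1 CPM, such as CG33462 in the non-infected libraries. The median log2 fold change of a list changed sign under another scaling for 2 lists that did not pass: without scale factors, detoxification went from 0.03 to -0.03 and insulin from 0.06 to -0.0012. The number of list members called also depended on scaling: without scale factors 2 fat body genes rose rather than 5, 5 Toll pathway genes fell rather than 3, and 5 iron genes rose and 1 fell rather than 7 and 0.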

Other observations

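Gene families recognised by their symbols, and chosen after the data were examined, moved beside the fixed lists. All 8 tested subunits of the cytosolic chaperonin CCT, which folds actin and tubulin, rose (median log2 fold change 0.52, from 0.30 for CCT8 to 0.71 for CCT5). Of 72 mitochondrial ribosomal protein genes 38 fell (median -0.28, lowest mRpL41 at -0.80). Of 28 seminal fluid protein genes named Sfp, which were not in the male list, 25 fell (median -0.83), and Sfp60F went from 736 ± 82 to 257 ± 5.8 CPM. Of 73 cytochrome P450 genes 30 fell and 5 rose (median -0.18). Cyp309a2 fell by 1.26 on the log2 scale, while Cyp9b1 rose by 1.36 ± 0.11. The camera p-values adjusted over these 4 families ran from 7.67e-17 to 3.69e-05. With an estimated correlation the adjusted p was 0.0205 for the Sfp and P450 families, 0.0755 for the mitochondrial ribosomal proteins and 0.0806 for CCT. Since the families were picked for moving, these p-values are not independent evidence.

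The rise of sisA was not shared by the 3 tested genes on either side of it on the X chromosome. At higher coordinates l(1)10Bb, Gapvd1 and Kap3 had log2 fold changes of 0.20 ± 0.09, 0.11 ± 0.06 and -0.06 ± 0.08, and at lower coordinates CG15198, CG44422 and CG11106 had 0.03 ± 0.06, 0.06 ± 0.09 and 0.04 ± 0.07. None of the 6 passed the test, against 7.91 ± 0.18 for sisA.

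In the paragraphs that follow, the tests of neighbouring genes and of other splits of the libraries were set before their results were seen. The tests on clock, muscle and male transcripts, and that of neighbours over 1000 bases apart, were chosen only after.

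Genes that rose lay next to each other more often than in random draws. Among the 242 genes that rose at least 2 times, 39 pairs of neighbours with non-overlapping models were found, against a median of 4 and a highest value of 13 in 10000 random draws of as many genes (one-sided permutation p = 0.0001, the smallest these draws can give). Without the 2 lists of immune peptides there were 26 pairs against a median of 3. With pairs over 1000 bases apart there were 8 pairs against a median of 1 (permutation p = 0.0003), so much of the excess lay in close neighbours such as the Bomanin genes. These values fit a hypothesis that part of the infection response is arranged in local clusters. Transcripts that run from an induced gene into the next could add to close pairs and were not tested. The random draws also took no account of gene families, and some pairs, such as NimB2 and NimB3, belong to the same family. Duplicated genes that lie side by side could therefore add to the pairs too, which was not tested.

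The 8 clock transcripts all differed between the groups. Library scaling is argued against by their direction, as the transcripts moved both ways. The smallest change of the 8, 0.25, also exceeded the largest shift of the median gene between scalings, 0.07. The 8 were taken up because all had passed the test, which favours changes above such a shift, so their size adds little. A different clock phase at sampling was looked at by setting transcripts that peak in the evening (tim, per, vri, Pdp1 and cwo) against those that peak in the morning (Clk and cry). Their mean log2 fold changes differed by -1.32, with all 5 of the first set lower and both of the second higher. These directions had been seen before the sets were compared, so the comparison cannot decide, and a difference of phase stays open. The clock transcript cyc was in neither set and rose by 0.48 on the log2 scale, so the comparison does not cover it. A difference of phase could come from collection at another time of day or from the infection, and the labels used here give no clock time.

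Nuclear respiratory transcripts fell together with muscle markers. Library scaling is argued against by the size of the fall, a median of -0.62 against a shift of at most 0.07 between scalings. An even loss of muscle tissue as the whole cause would lower alike all markers that are made in muscle alone. The changes of the 23 tested markers differed by far more than their errors (Cochran Q over its degrees of freedom 30.8, and 26.3 without the actin genes). Of the 23 markers 3 rose, or 1 of 19 without the actin genes. An uneven loss between muscle types, or markers made elsewhere, could also give such a spread, so the test cannot exclude a lower share. Lower transcript levels within muscle, fat body or other tissues of infected flies, and the effect of the wound, may contribute and were not tested.

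Accessory gland transcripts fell and testis transcripts did not. Of 19 accessory gland genes 17 fell (median log2 fold change -1.06), and of 15 testis genes 1 rose and 14 did not pass (median -0.014), which argues against a lower share of males or of the whole male reproductive tract. Yolk protein transcripts, a female product, were near 0 in both groups (Yp2 at 7 counts or fewer per library), which also argues against a changed share of the sexes. The fall was not confined to the gland: the ejaculatory duct gene Dup99B fell, and the ejaculatory bulb gene EbpII fell by 1.46 on the log2 scale. An even loss of accessory gland tissue as the whole cause would lower its transcripts alike, but the Cochran Q over its degrees of freedom was 23.9. Acp54A1 fell by 1.94 on the log2 scale while Acp32CD stood at -0.02 ± 0.07. The same ratio was 15.97 without Acp32CD. An uneven loss of cells of the gland could also give such a spread, so the test cannot exclude a lower share. The expression of secretory genes within the gland may have changed, with the infection, the wound or the mating state of the flies behind it. Such a change was not tested and would not cover Dup99B or EbpII.

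The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2980 genes and was the only 1 of the 10 with as many. The highest of the other 9 gave 0 genes with edgeR. At an unadjusted p under 0.05, these 9 gave 153 to 380 genes, against 4312 for the real split. Each of the other 9 mixed infected and non-infected libraries in both groups, so a difference with infection widened the spread within groups. Few calls there follow from the mixing, and the splits cannot decide.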
